A study of Danio rerio with 6 samples.

How the data were processed

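ZMEL1, a cell line derived from a zebrafish melanoma, was profiled by bulk RNA sequencing after serum starvation for 2 h and a further 2 h with recombinant human TGFB1 at 10 ng/mL or with its vehicle. The labels put 3 samples in the TGFB1 group and 3 in the vehicle group, and call the triplicate technical. Per the submitters' processing notes, cutadapt, TopHat2 version 2.1 and HTSeq were used on the zebrafish build GRCz11.

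The deposited table of gene counts holds 6 value columns whose names match no title, description, characteristic or protocol of any sample. Taking the groups from the order of the columns or from the counts would have been a guess. The 6 columns were therefore not used, no counts were analysed, and neither depth nor precision per sample is given. Only the header line and the column of gene identifiers were read.

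The identifiers were looked up in a table that pairs Ensembl gene identifiers with symbols. The 27 lists of genes, written before the data were examined, were then looked up by symbol. A gene counted as found where any of its listed names matched, with upper and lower case treated alike. All tests and alternatives planned for the comparison of TGFB1 with vehicle were left undone, and the rule for naming genes by their change was not applied.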

Results

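The series was designed to ask which genes respond to TGFB1, a secreted ligand that signals through receptor kinases and SMAD proteins, in the zebrafish melanoma line ZMEL1. The labels describe 6 RNA-seq samples, 3 treated with TGFB1 and 3 with vehicle. No expression level, fold change or test is reported here. Only the labels of the samples and the text of the series were searched for the column names. By these, 0 of the 6 value columns of the deposited table could be tied to a sample. The comparison of TGFB1 with vehicle was therefore not made, and nothing is stated about whether any gene rose or fell.

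The table lists 32520 distinct zebrafish Ensembl gene identifiers. A symbol was found for 29201 of them (89.8%), and the other 3319 were left unnamed. Of the 957 distinct genes in the lists written for this comparison, 713 were matched by name. With upper and lower case treated alike, 1806 symbols belonged to several identifiers, so a match need not point to a single identifier. A gene that was not matched may stand in the table under another symbol, so these counts describe the matching of names and not expression in ZMEL1.

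Among inhibitors of TGF-beta and SMAD signalling, 8 of 17 listed genes were matched. They included smad7, an inhibitory SMAD (ENSDARG00000016858), skilb (ENSDARG00000022904) and pmepa1 (ENSDARG00000039325). Among the ligands, receptors, SMADs and latent binding proteins of the pathway, 18 of 33 were matched, including tgfb1a (ENSDARG00000041502), tgfb1b (ENSDARG00000034895) and smad2 (ENSDARG00000006389). Of the 43 genes listed as early targets in mammalian cells, 32 were matched. Matches were found for 25 of the 35 melanocyte genes, including tyr (ENSDARG00000039077) and dct (ENSDARG00000006008), which encode enzymes of melanin synthesis. The interferon and antigen presentation list had 51 of 60 members matched, and the cytokine and NF-kappaB list 53 of 60. All 13 mitochondrially encoded transcripts on their list were matched.

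Of 23 genes chosen in advance to be reported whatever their change, 13 were matched by their own symbol and 10 were not. The unmatched symbols were tgfbr1a and tgfbr2b (TGF-beta receptors), smad3a, smad3b and smad4a (SMAD proteins), skila, junba, junbb, id2a and mitfa (a regulator of the melanocyte lineage). Of these 10, 2 (tgfbr2b and smad4a) were matched in the list of pathway components under another listed name. No identifier is given for these 2, since identifiers were recorded only under each gene's own symbol.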

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

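All settings in this part were chosen after the table had been seen, and no other normalization, filter or test of the counts was run, since no value column was used. The sample titles use the same replicate numbers in both groups but do not state that equal numbers form a pair. No paired analysis was possible because no column could be tied to a replicate number. Matching column names by their digits also tied 0 of 6 columns to a sample. Matching by accession gave 0 as well, but the first search had already covered the accessions, so this adds nothing. Using only the first listed name of each gene matched 690 listed genes instead of 713. Respecting upper and lower case matched 329, because that setting excludes symbols which the name table writes in capitals.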
